A study of Homo sapiens with 101 samples.

How the data were processed

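CTCF and RAD21 ChIP-seq peak lists from isolated HAP1 nuclei were analysed as deposited. Bowtie, HOMER and deepTools and the genome build hg19 are named per the submitters' processing notes, and no versions are given in the sources used here. The deposited values are peak positions (chromosome, start and end), and the authors' lists hold no height, fold, score or p-value for a peak. The NB CTCF and NB nRAD21 lists of replicate 2 carry a HOMER header. Per the file headers, they were called in factor style against the NB IgG library at a false discovery rate of 0.001, with at least 4-fold more tags than the input and than the surrounding 10000 bp, and a Poisson p-value of 0.0001 over input. The same headers give 34721 putative CTCF peaks and 14789 putative nRAD21 peaks, of which 3426 and 3076 were removed against the input, and fragment lengths of 194 and 248 bp. The remaining 7 lists have no header. Their caller, threshold and depth are not given in the sources used here. Each of these lists belongs to 1 sample. A difference in depth or threshold between lists changes how many weak sites are listed, and so moves every share of a list that has a partner.

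Groups and replicate numbers were taken from the sample titles. The replicate 2 lists of NB name no sample in the record of the files and were matched to the NB CTCF and NB nRAD21 samples of replicate 2 by title. Nothing in the labels says that replicates came from separate cultures, so p-values and spreads measure only these samples and the spread may be technical. Some ChIP-seq samples carry the characteristics of a Hi-C protocol, while their titles and extraction protocol are those of ChIP-seq. All per-sample columns of positions were used.

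A peak was counted as shared when it had at least 1 bp in common with a peak of the other list. Shares are given with 95% Wilson intervals, which cover counting error only. Chance was estimated by shifting 1 list circularly along each chromosome by a random distance, 1000 times per overlap, with a one-sided permutation test. The 36 p-values were adjusted by the Benjamini-Hochberg method. Shifts of 50 kb to 1 Mb in either direction, 100 per overlap, which keep the regional density of sites, gave a mean of 0.455 to 1.27% of peaks with a partner. Merged regions are unions of peaks that share at least 1 bp. NB values are means over replicates 2 and 7 with the SD; fNu and WT-NB have 1 list per antibody. The share of CTCF peaks with nRAD21 was compared between conditions by an exact permutation test, whose smallest p with 2 values against 1 is 0.333, and the other differences between conditions were not tested. CTCF and nRAD21 lists were compared within the same condition and replicate number, and the alternative across numbers was computed. Coordinates are on hg19 and counted from 1. In the line order comparisons, partner labels were permuted 10000 times within the list.

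The design fixed before the data were examined assumed a score per peak. Because the lists hold none, the comparison of scores with and without a partner was replaced by the line order of the 2 lists with a header, and the alternatives with a stricter threshold or lists of equal length were not run. The rule for named regions was the 3 highest-scored peaks of each list and of each comparison, which was applied to line order in the same 2 lists only. Regions with RAD21 in all lists and CTCF in none were named after their values were seen. The rule for named genes, the gene lists fixed beforehand, the position of peaks relative to genes and the CTCF motif scan need an annotation or sequence of hg19, which was not used here, so no gene is named.

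Overlaps were computed with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The overlap routine was checked against bedtools 2.31.1 on all 72 ordered pairs of lists and differed at 0 peaks. It was also tested on simulated data made from the 25879 sites of NB CTCF replicate 7, where planted shares were recovered within 0.413 percentage points and a list with no planted sharing gave a permutation p of 0.174. The side of planted offsets was recovered at 100% of simulated sites, but the planted jitter was smaller than the offset, so no side could change. That check also used another routine than the side results below and does not test them. A planted stretch of early lines was found on its chromosome with both edges within 1 Mb. Alternatives were an overlap of at least 50% of both peaks, centres within 500 bp, chromosomes 1 to 22 and X alone, peaks within 500 bp merged or joined, lists paired across replicate numbers, and each NB replicate left out.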

Results

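Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map CTCF, the zinc-finger protein that binds an asymmetric DNA motif and is known to block loop extrusion, and RAD21, the subunit that closes the cohesin ring, in nuclei isolated from HAP1-RAD21-TEV cells. HAP1 is a near-haploid human line derived from a chronic myelogenous leukaemia line, and in this derivative RAD21 carries sites for TEV protease, so that the ring can be opened in isolated nuclei. The series holds 101 samples, of which 67 are in Hi-C groups and 34 in ChIP-seq groups. Peak lists of 9 ChIP-seq samples were analysed here, and the Hi-C samples, the protease-treated samples and the samples in salt-containing buffer were not analysed here. Of the 9 lists, 4 are for CTCF, 4 for the antibody labelled nRAD21 and 1 for the antibody labelled cRAD21, names used in the study for antibodies against the N-terminal and the C-terminal part of the protein. Nuclei labelled NB were kept in a low-salt buffer with 10 mM KCl. NB has 2 lists for CTCF and 2 for nRAD21 (replicates 2 and 7) and 1 for cRAD21 (replicate 7). The groups labelled fNu, a term the labels do not define, and WT-NB each have 1 CTCF list and 1 nRAD21 list, both of replicate 2. The WT-NB samples are titled WT but carry the same cell line label as the others.

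CTCF peaks outnumbered RAD21 peaks in every condition. The NB CTCF lists held 30108 peaks (replicate 2) and 25879 peaks (replicate 7), with a mean of 27993.5 ± 2990 (SD, n = 2). The fNu list held 25346 CTCF peaks and the WT-NB list 22143. For nRAD21, NB had 10726 peaks (replicate 2) and 14126 peaks (replicate 7), a mean of 12426 ± 2404 (SD, n = 2), against 17953 in fNu and 16142 in WT-NB. The cRAD21 list of NB replicate 7 held 14683 peaks. Neighbouring CTCF peaks lay a median of 45.4 to 59.6 kb apart in the 4 lists, and neighbouring RAD21 peaks a median of 79.7 to 112 kb apart in the 5 lists. Each list used 1 fixed peak width, between 362 and 431 bp. Sequencing depth was stated for the NB replicate 2 lists alone, 28279568 tags for CTCF and 24729656 for nRAD21, with 7.46% and 1.55% of tags in peaks as estimated by the caller. Depth is unknown for the remaining 7 lists, so a peak missing from a list was not detected at that list's depth and threshold and is not shown to be absent.

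Among chromosomes 1 to 22 and X, chromosome 19 was the most densely occupied in all 9 lists, followed by chromosome 17. In NB replicate 2 chromosome 19 carried 20.6 CTCF peaks and 8.64 nRAD21 peaks per Mb. Of the same chromosomes, chromosome 21 had the fewest CTCF peaks per Mb in all 4 CTCF lists, 5.20 in NB replicate 2, so that the most and least dense of them differed 3.95-fold in that list. Peaks were divided by the span from the chromosome start to the last peak end in any list, 48.1 Mb for chromosome 21. Unsequenced stretches were not taken out of this span, here or in the trends over chromosomes below, so they lower the density of chromosomes that hold them. Among regions held by all 9 lists, the 1-Mb window with the most was on chromosome 1 (hg19, positions 156000001 to 157000000), with 23 regions. The next was on chromosome 19 (45000001 to 46000000), with 18. The median over the 2095 windows that held any such region was 3. No gene was assigned to a peak, because no annotation of hg19 was used here.

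The replicates of NB gave the yardstick for every other comparison. Of the CTCF peaks of replicate 7, 94.9% (95% Wilson interval 94.6 to 95.1%) shared at least 1 bp with a peak of replicate 2, and 81.6% (81.1 to 82.0%) of the longer replicate 2 list was found in replicate 7. The nRAD21 lists overlapped less evenly: 82.9% (82.2 to 83.6%) of replicate 2 was found in replicate 7, and 63.0% (62.2 to 63.8%) of replicate 7 in replicate 2. The base-pair Jaccard index was 0.672 for CTCF and 0.472 for nRAD21. Circular shifts of the lists along each chromosome gave 0.314 to 0.816% of peaks with a partner in these 4 overlaps. Across the 36 overlaps tested, the observed share was 103 to 220 times the mean of the shifts, and each had a one-sided permutation p of 0.001, the smallest that 1000 shifts can give (Benjamini-Hochberg adjusted p = 0.001). Intervals cover counting error only, since peaks of a list are not independent replicates. The yardstick is limited for nRAD21. There NB replicate 7 had a higher Jaccard index with fNu (0.566) and WT-NB (0.572) than with NB replicate 2. NB replicate 2 had 0.423 with fNu and 0.433 with WT-NB. For CTCF, NB replicate 7 had 0.685 with fNu and 0.664 with WT-NB. The NB replicate 2 lists also came in another form, with a header, so the spread between NB replicates may include that difference.

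**Figure D1:**
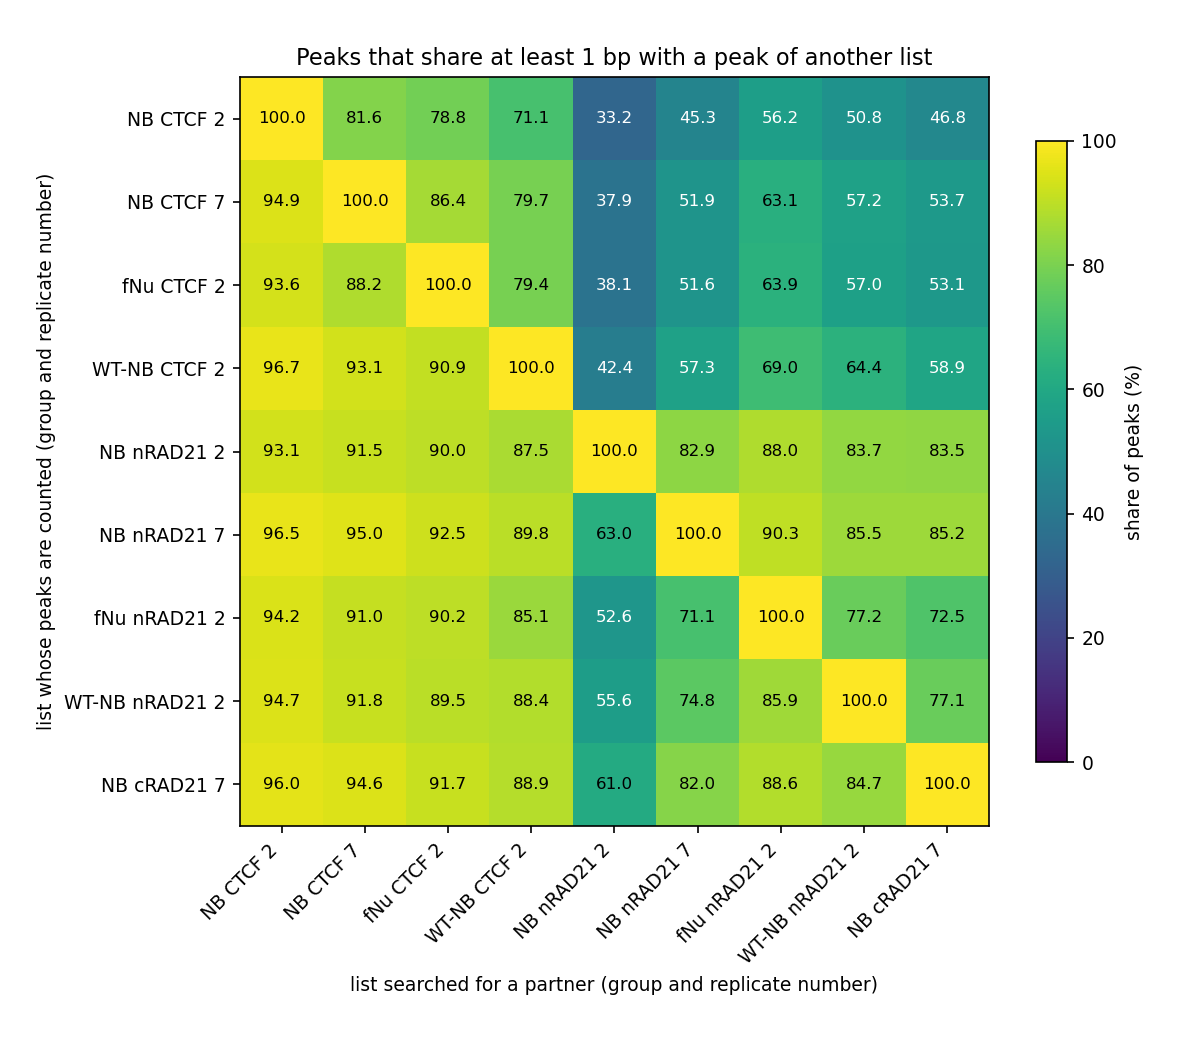
Share of the peaks of each list (rows, group and replicate number) that share at least 1 bp with a peak of another list (columns), in percent. RAD21 lists are found largely in CTCF lists (for example 93.1% of nRAD21 in NB replicate 2), while CTCF lists are found in RAD21 lists in part (33.2% in NB replicate 2).

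RAD21 peaks lay mostly at CTCF peaks, whereas many CTCF peaks had no listed RAD21 peak. This comparison addresses where cohesin and CTCF sit together in isolated nuclei. In NB, 94.1% ± 1.32 (SD, n = 2) of nRAD21 peaks overlapped a CTCF peak of the same replicate. In fNu the share was 90.2% (89.7 to 90.6%) and in WT-NB 88.4% (87.9 to 88.9%). In the other direction, 33.2% (32.7 to 33.7%) of CTCF peaks of NB replicate 2 and 51.9% (51.3 to 52.5%) of those of NB replicate 7 overlapped an nRAD21 peak, a mean of 42.5% ± 13.2 (SD, n = 2). The shares were 63.9% (63.3 to 64.5%) in fNu and 64.4% (63.8 to 65.1%) in WT-NB. Each nRAD21 list was shorter than its CTCF list, 10726 against 30108 peaks in NB replicate 2 and 17953 against 25346 in fNu. List length therefore limits these shares, and a CTCF peak without nRAD21 is not shown to lack cohesin. In NB replicate 2 the caller estimated 1.55% of tags in peaks for nRAD21 and 7.46% for CTCF. The cRAD21 antibody gave values close to nRAD21 of the same replicate: 94.6% (94.2 to 94.9%) of its peaks had a CTCF partner, and 53.7% (53.1 to 54.3%) of CTCF peaks had a cRAD21 partner.

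The share of CTCF peaks with nRAD21 was 21.4 percentage points higher in fNu and 21.9 points higher in WT-NB than the NB mean, which is 1.62 and 1.66 times the SD of the NB pairs. A two-sided exact permutation test gave p = 0.667 for each, and with 2 pairs against 1 it cannot give a p below 0.333. NB replicate 2 decides much of the size: against NB replicate 7 alone, whose list has the same form as the fNu and WT-NB lists, the differences were 12.0 and 12.6 points. Over the 19255 regions with CTCF in all 4 CTCF lists, a set chosen after the lists were examined, an nRAD21 peak was present at 47.4% (NB replicate 2), 63.3% (NB replicate 7), 75.3% (fNu) and 69.4% (WT-NB). These shares followed the order of the nRAD21 lists' lengths, from 10726 peaks in NB replicate 2 to 17953 in fNu, so condition and list length cannot be separated.

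**Figure D2:**
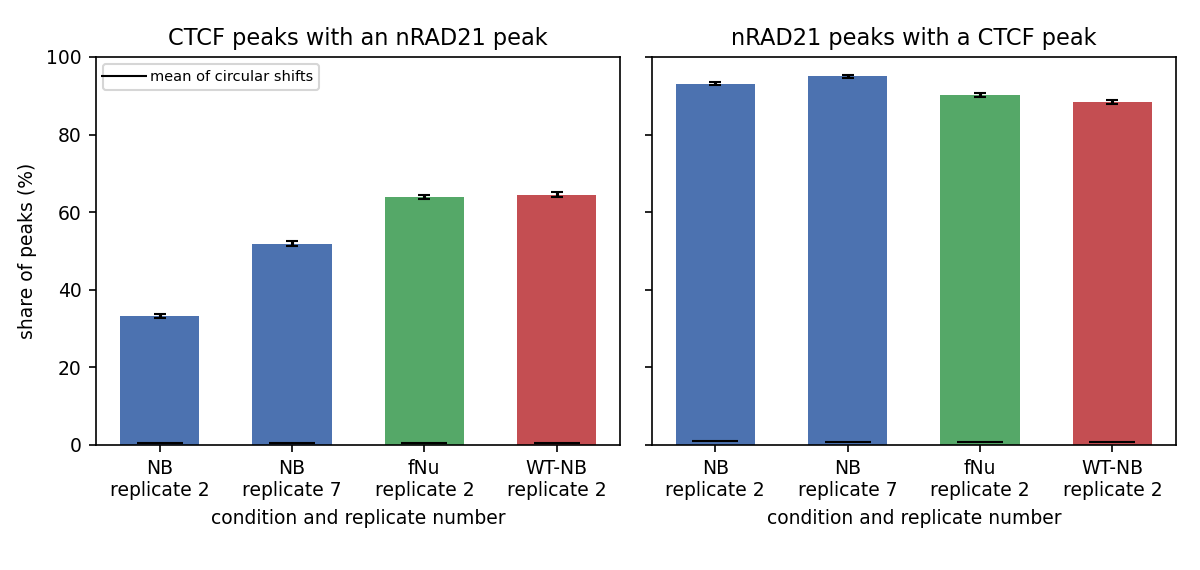
Share of CTCF peaks with an nRAD21 peak (left) and of nRAD21 peaks with a CTCF peak (right), in percent, for the 4 pairs of lists of the same condition and replicate number. Bars are shares with 95% Wilson intervals and horizontal marks the mean of 1000 circular shifts. The left shares run from 33.2 to 64.4% and the lowest on the right is 88.4%.

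Individual regions illustrate both classes. The earliest nRAD21 peak in the line order of NB replicate 2 lay on chromosome 15 at 74419858 to 74420288, with a peak in all 4 CTCF and all 5 RAD21 lists, and the next, on the same chromosome at 81071249 to 81071679 and 68155713 to 68156143, were held by all 9 lists too. All of these lie in the stretch of chromosome 15 with many early lines that is described below. Among nRAD21 peaks of NB replicate 2 without a CTCF partner in that replicate, the earliest was on chromosome 22 at 46374440 to 46374870, found in all 5 RAD21 lists and in 0 CTCF lists. The earliest CTCF peak with a partner in all 4 CTCF lists and in 0 RAD21 lists, among the first 3 CTCF peaks without nRAD21 in replicate 2, was on chromosome 1 at 180992005 to 180992413. The first line of the same list was a mitochondrial peak (chromosome M, 2566 to 2974), present in both NB CTCF lists and in neither the fNu nor the WT-NB list. No filter for artefact-prone regions was applied here, so this peak is not shown to be a site bound by CTCF.

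The 2 RAD21 antibodies marked largely the same sites in NB replicate 7. Of the nRAD21 peaks, 85.2% (84.6 to 85.8%) had a cRAD21 partner, and 82.0% (81.4 to 82.6%) of cRAD21 peaks had an nRAD21 partner, with a base-pair Jaccard index of 0.630. Between the nRAD21 replicates of NB the corresponding shares were 82.9 and 63.0%. Peaks seen with a single antibody were less often found elsewhere. CTCF of the same replicate was present at 97.5% (97.2 to 97.8%) of nRAD21 peaks with a cRAD21 partner and at 80.7% (79.0 to 82.3%) of the 2088 without one. For cRAD21 the corresponding shares were 97.5% (97.2 to 97.8%) and, among the 2645 peaks without an nRAD21 partner, 81.2% (79.7 to 82.7%). The fNu nRAD21 list held 94.8% (94.4 to 95.2%) of the nRAD21 peaks with a cRAD21 partner and 64.4% (62.3 to 66.4%) of those without. There is 1 list per antibody here, so the difference between antibodies has no replicate check.

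Most nRAD21 sites of nuclei kept in NB were also found in fNu, while a larger part of the fNu sites was not listed in NB. The comparison addresses whether nuclei kept in NB hold the same sites as fNu. Of the NB nRAD21 peaks, 89.2% ± 1.64 (SD, n = 2) had a partner in fNu, while 61.8% ± 13.1 (SD, n = 2) of fNu nRAD21 peaks had one in NB. Each SD here is over the 2 NB lists, because fNu has 1 list per antibody. For CTCF, 82.6% ± 5.36 (SD, n = 2) of NB peaks were found in fNu and 90.9% ± 3.82 (SD, n = 2) of fNu peaks in NB. The differences between NB and fNu in these overlaps were not tested, and shares in either direction depend on the lengths of the lists. Between the NB replicates, 82.9% of replicate 2 and 63.0% of replicate 7 nRAD21 peaks had a partner in the other list. An asymmetry of this kind therefore appears within NB too. For CTCF the shares between the NB replicates were 81.6% (replicate 2) and 94.9% (replicate 7). Of the 8403 regions with RAD21 in all 3 NB lists, 195 (2.32%, 2.02 to 2.66%) had no fNu peak, and of the 24567 regions with CTCF in both NB lists, 2668 (10.9%, 10.5 to 11.3%) had none. In the opposite direction, 3152 RAD21 regions and 1158 CTCF regions of fNu, from lists of 17953 and 25346 peaks, were in no NB list. The 2 directions are not comparable, because NB regions had to be in every NB list of the protein and fNu regions in 1 list. The RAD21 and CTCF shares are not comparable either, with 3 NB lists required for RAD21 and 2 for CTCF. The earliest nRAD21 peak of NB replicate 2 shared with replicate 7 and missing from fNu lay on chromosome 1 at 17033865 to 17034295, and the next on chromosome 1 at 54953786 to 54954216, a region in 4 RAD21 lists and 0 CTCF lists. For CTCF, after the mitochondrial peak, the earliest was on chromosome 8 at 82754484 to 82754892, held by the NB CTCF lists alone.

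The WT-NB lists were compared with NB to ask whether the samples titled WT hold the same sites. These samples carry the cell line label of the line with protease sites in RAD21. The labels therefore do not establish a difference of line. Of the NB CTCF peaks, 75.4% ± 6.06 (SD, n = 2) were found in WT-NB, and 94.9% ± 2.51 (SD, n = 2) of the shorter WT-NB list was found in NB. For nRAD21, 84.6% ± 1.24 (SD, n = 2) of NB peaks had a WT-NB partner, and 65.2% ± 13.6 (SD, n = 2) of WT-NB peaks had an NB partner. Each SD here is over the 2 NB lists, because WT-NB has 1 list per antibody. Between the NB nRAD21 replicates, the shares were 82.9% (replicate 2) and 63.0% (replicate 7), so an asymmetry of this kind appears within NB too. Of the regions with RAD21 in all 3 NB lists, 421 (5.01%, 4.56 to 5.50%) lacked a WT-NB peak, and 70 lacked both a WT-NB and a fNu peak. In the opposite direction, 2309 RAD21 regions and 484 CTCF regions of WT-NB, from lists of 16142 and 22143 peaks, were in no NB list. These come from 1 list each, so the 2 directions are again not comparable. Of the RAD21 regions in no NB list, 1039 were in both fNu and WT-NB, and 652 of these (62.8%, 59.8 to 65.6%) had CTCF in all 4 lists. Among all regions held by 2 RAD21 lists, 1716 had CTCF in all 4 lists, 489 in 3, 272 in 2, 180 in 1 and 248 in 0. A majority with CTCF in all 4 lists was therefore not particular to the regions missing from NB. The earliest NB nRAD21 peak in both replicates and missing from WT-NB was on chromosome 12 at 122232102 to 122232532, in all 4 CTCF lists and 4 RAD21 lists. The fNu and WT-NB lists overlapped each other by 77.2% (76.6 to 77.8%) of fNu nRAD21 peaks and 85.9% (85.4 to 86.4%) of WT-NB nRAD21 peaks. The differences between NB and WT-NB in these overlaps were not tested.

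Merging all lists gave 34871 regions, which fell into a shared core and a large fringe. CTCF was present in all 4 lists at 19255 regions (55.2%, 54.7 to 55.7%). RAD21 was in all 5 lists at 7497 of these (38.9%, 38.2 to 39.6%), in some lists at 8742 and in none at 3016 (15.7%, 15.2 to 16.2%). At the other end, 6160 regions (17.7%, 17.3 to 18.1%) were held by a single list. RAD21 without CTCF was rare and seldom shared: 1941 of the regions with RAD21 in any list (8.65%, 8.29 to 9.02%) had CTCF in no list, and 1583 of these (81.6%, 79.8 to 83.2%) came from 1 list. RAD21 was in all 5 lists and CTCF in none at 13 regions, 0.165% (0.0967 to 0.283%) of the 7857 regions with RAD21 in all 5. They include chromosome 2 at 30929799 to 30930286 and 70530985 to 70531444, chromosome 17 at 31082037 to 31082519 and chromosome X at 102206418 to 102206887. Without the NB replicate 2 lists, a setting chosen after the data were examined, 57 regions had RAD21 in all remaining lists and CTCF in none.

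**Figure D3:**
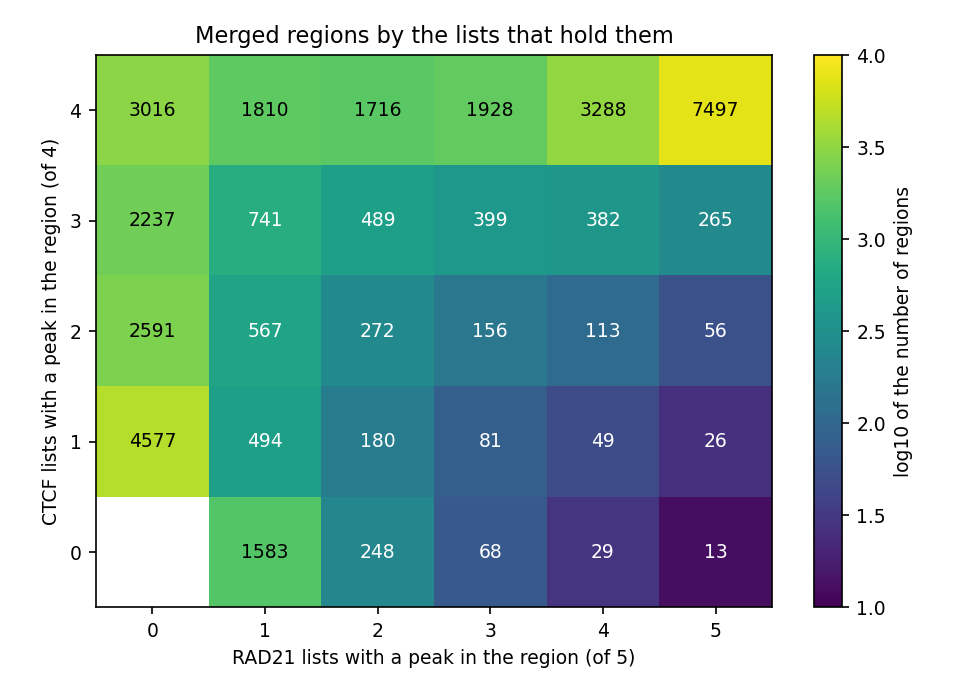
Number of merged regions by how many of the 4 CTCF lists (vertical axis) and of the 5 RAD21 lists (horizontal axis) hold a peak in them, coloured by log10 of the number. The largest class, 7497 regions, has all lists, and 13 regions have RAD21 in all 5 lists and CTCF in none.

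nRAD21 peaks that lay on a CTCF peak of any list were found again in another RAD21 list more often than those that did not. In NB replicate 2, 97.5% (97.2 to 97.8%) of the 10087 nRAD21 peaks with CTCF were present in another RAD21 list, against 24.3% (21.1 to 27.7%) of the 639 without. In NB replicate 7 the shares were 97.6% (97.4 to 97.9%) and 55.9% (50.2 to 61.4%), in fNu 90.3% (89.8 to 90.7%) and 34.0% (30.5 to 37.7%), and in WT-NB 94.0% (93.6 to 94.3%) and 39.2% (35.1 to 43.3%). Peaks were not matched for line order, described next. In NB replicate 2, nRAD21 peaks with a CTCF partner of that replicate had a median line percentile of 47.5, against 76.3 without. The contrast is therefore not separated from line order.

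Peaks early in the line order of the NB replicate 2 lists were found elsewhere more often than late ones. The lists carry no score, and the order of lines, whose meaning their headers do not state, was used as a within-list rank after the lists had been examined. NB CTCF peaks with a replicate 7 partner had a median line percentile of 41.0, against 87.5 for those without. The medians were 23.3 with an nRAD21 partner and 64.0 without. NB nRAD21 peaks with a replicate 7 partner had a median of 42.8, against 77.4 without. Each of the 8 comparisons had a two-sided permutation p of 0.0001, the smallest that 10000 permutations of the partner labels can give, and peaks are not biological replicates. In the earliest 10% of CTCF lines, 77.2% (75.6 to 78.6%) of peaks had an nRAD21 partner of the same replicate, and in the latest 10% 2.92% (2.38 to 3.59%). Late lines were found elsewhere too: of the latest 10% of CTCF lines, 23% (21.5 to 24.6%) were in replicate 7, and of the latest 10% of nRAD21 lines, 60.4% (57.4 to 63.3%) were in replicate 7, 72.6% (69.9 to 75.2%) in fNu and 85.5% (83.2 to 87.4%) had CTCF.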

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

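The tests of the side shared by different lists, of neighbouring sites, of equally dense windows, of the stretch found in the nRAD21 list and of NB replicate 7 against fNu were chosen only after the results had been seen.

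The line order of the NB replicate 2 lists was uneven along the genome, most of all on chromosome 15: 46.3% of 464 CTCF peaks between 62 and 90 Mb were in the first 10% of lines, against 9.43% elsewhere, and 45.5% of 222 nRAD21 peaks between 61 and 90 Mb, against 9.24% elsewhere, with edges at most 1 Mb apart. The next CTCF stretches were chromosome 19 from 0 to 52 Mb, with 24.1% of 1110 peaks early, and chromosome 9 from 129 to 141 Mb, with 29.8% of 238, where the nRAD21 list had 22.2% of 144 between 126 and 141 Mb. For the chromosome 15 stretch as found in the nRAD21 list, CTCF peaks with no RAD21 peak in any list, which did not enter that search, came 29.5 percentile points earlier inside than outside, which argues against more RAD21 on that stretch alone. The stretch was denser in CTCF peaks than 95.8% of windows of its size, so density may contribute. Among the CTCF peaks with no RAD21 peak, the 21 windows at least as dense shifted by at most 9.42 points, which argues against density alone. These windows lay on 5 chromosomes and were placed every 5 Mb, so neighbouring ones overlap and they are not 21 separate stretches. Over all CTCF peaks, used in the search, the values were 37.7 for the stretch and at most 22.2 for windows as dense. An additional copy of the stretch remains a candidate explanation, since HAP1 cells are known to carry an extra piece of chromosome 15, but copy number was not measured here and line order stands in for peak strength only by assumption.

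The difference between NB and fNu in the share of CTCF peaks with nRAD21 varied with the density of CTCF peaks over 23 chromosomes, which are not replicates. For NB replicate 7 minus fNu, Pearson's r was 0.664 (two-sided permutation p = 0.00035) and Spearman's rho 0.748 (permutation p = 7e-05, Benjamini-Hochberg adjusted p = 0.00031 over 9 relations), and r was 0.651 without chromosomes 19 and 17, which argues against NB replicate 2 alone as the source of the difference. Each list's own slope was weaker, with r = 0.401 (permutation p = 0.067) and rho = 0.498 (adjusted permutation p = 0.037) in NB replicate 7, r being 0.322 without the same chromosomes. In fNu rho was -0.392 (adjusted permutation p = 0.088). In WT-NB r was -0.300 (permutation p = 0.16) and rho 0.0850 (adjusted permutation p = 0.7). For NB replicate 7 minus WT-NB rho was 0.454 (adjusted permutation p = 0.056), and r fell from 0.629 to 0.297 without chromosomes 19 and 17. A list that reaches only the earliest CTCF sites may account for the trend in NB replicate 2, where rho was 0.655. With 10 classes of CTCF line order weighted equally, rho became -0.388 (adjusted permutation p = 0.088), with r = -0.509 (permutation p = 0.013, and -0.224 without chromosomes 19 and 17). With 5 classes of at least 36 peaks on every chromosome, rho was -0.329 (adjusted permutation p = 0.14), with r = -0.486 (permutation p = 0.019, and -0.229 without them). Replicate 7 has no line order, so this explanation stays open for it, as does a difference between the conditions, which 1 fNu list cannot separate from its depth or threshold.

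Where RAD21 and CTCF peak centres were at least 20 bp apart, RAD21 lay mostly on a repeatable side of CTCF. Over 7741 regions the median distance was 25 to 31 bp. NB replicate 7 and fNu had the same side at 74.9% of the 2936 sites with at least 20 bp in both (one-sided permutation p = 0.001, the smallest 1000 shuffles can give). The range was 67.1 to 77.1% over the 6 pairs of conditions and replicates, lowest for NB replicate 2 with fNu. With any offset, 3457 of the 7741 regions had the same side in NB replicate 7, fNu and WT-NB. Centres displaced in any pair of libraries would also give a shared side between lists of 1 protein, where the highest share was 51.4%. A displacement that differs between CTCF and RAD21 libraries would cancel in that comparison, which therefore cannot address it. A property of each site, such as the direction of the CTCF motif, which was not scanned here, is a candidate explanation. Among the 3457 regions with the same side in NB replicate 7, fNu and WT-NB, where neighbours are the next such regions and not the next peaks, RAD21 lay with any offset, the definition tried first, on the outer sides of 46.8% of 141 neighbouring pairs 5 to 20 kb apart (highest shuffle 39.0%) and of 35.5% of 521 pairs 20 to 100 kb apart (highest shuffle 30.9%), which argues against independent sides at these distances, while at 100 kb to 1 Mb outer sides were 24.0% of 1988 pairs (adjusted permutation p = 0.3433) and inner sides 27.9% (adjusted permutation p = 0.008). Requiring 20 bp, tried next, left 1237 regions. At 5 to 20 kb 25% of 12 pairs were on the outer sides, too few to decide. At 20 to 100 kb the share was 40.3% of 67 pairs, under the highest shuffle at 41.8% (two-sided permutation p = 0.008, Benjamini-Hochberg adjusted p = 0.0142 over 16 tests). At 100 kb to 1 Mb outer sides were 28.4% of 489 pairs (adjusted permutation p = 0.0736) and inner sides 23.1% (adjusted permutation p = 0.3815). With any offset the inner share there, 27.9%, only equalled its highest shuffle. Outer and inner pairs must alternate along a chromosome, so the 16 tests are not separate evidence.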

How the results depend on the processing

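The alternatives with regions of CTCF in all 4 lists, with the earlier lines of NB replicate 2 and with merged regions without NB replicate 2 were chosen after seeing the data. All 91 shares under an alternative stayed above chance in a one-sided permutation test (p = 0.005, the smallest that 200 shifts can give), which shares so far above chance could hardly fail. The 20 shares fell by at most 0.746 points with an overlap of 50% of both peaks and rose by at most 0.257 points with centres within 500 bp. Without NB replicate 2, where fewer lists are required, regions with RAD21 in all lists and CTCF in none went from 13 to 57, and those with CTCF and RAD21 in all lists from 7497 to 9942. Without the replicate block, pairing NB lists across numbers, 41.6% of NB CTCF peaks had nRAD21 and 94.0% of nRAD21 peaks had CTCF, against 42.5% and 94.1% in the paired comparison. Leaving out 1 NB replicate gave differences in the share of CTCF peaks with nRAD21 of 12.0 to 30.7 points for fNu minus NB and 12.6 to 31.2 for WT-NB minus NB, and 33.2 to 51.9% of NB CTCF peaks with nRAD21, 52.6 to 71.1% of fNu nRAD21 peaks in NB and 55.6 to 74.8% of WT-NB nRAD21 peaks in NB. The earlier 50% of lines of NB replicate 2 were found in replicate 7 at 99.2% for CTCF and 95.4% for nRAD21. Stricter thresholds, lists of equal length, positions relative to genes and motif distances were not run, because they need scores or a genome of hg19. Depth is unknown for 7 lists and limits every statement on missing peaks.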

Other observations

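The tests of distance and of neighbouring sites here were chosen after the data were examined. RAD21 regions without CTCF lay nearer to CTCF sites than shifted regions did. The 110 regions with RAD21 in at least 3 lists and CTCF in none were a median of 10.6 kb from the nearest region with CTCF, against 42.1 kb after circular shifts and 31.1 kb after shifts of 50 kb to 1 Mb, which keep the regional density of sites. The two-sided permutation p was 0.002 with either, the smallest that 1000 shifts can give. The 1583 such regions from 1 RAD21 list were a median of 19.2 kb away, against 41.1 and 28.1 kb after the same shifts (permutation p = 0.002 with either).

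Regions with CTCF in all 4 lists differed in line order with their RAD21. The 7497 with RAD21 in all 5 lists had a median percentile of 19.7 in the NB CTCF replicate 2 list, and the 3016 with RAD21 in none 51.1. On the stretch of chromosome 15 described above, 59.9% of CTCF peaks in NB replicate 7, 70.4% in fNu and 70.5% in WT-NB had nRAD21, against medians of 50.9, 63.7 and 64.4% over windows of its size. The highest of those windows had more, 60.6, 72.6 and 75%. In NB replicate 2, whose line order was used to find the stretch, its share was 45% and that of the highest other window 44.2%.

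Neighbouring sites here are successive members of the regions with the same side in NB replicate 7, fNu and WT-NB, 3457 with any offset and 1237 with at least 20 bp, so other CTCF peaks can lie between them. For those over 1 Mb apart, with any offset, RAD21 lay on the inner sides of 30.8% of 746 pairs, above the highest of the shuffles at 29.0%. With at least 20 bp the share was 29.1% of 640 pairs, just under the highest of the shuffles at 29.4%. Over 16 such tests of outer or inner sides, the adjusted two-sided permutation p of these shares was 0.0053 with any offset and 0.008 with at least 20 bp. RAD21 lay on the outer sides of 20.2% of the same pairs with any offset (adjusted permutation p = 0.0053) and of 23.1% with at least 20 bp (adjusted permutation p = 0.368). Apart from pairs on the same side, outer and inner pairs alternate along a chromosome. More outer pairs at shorter distances therefore force more inner pairs at longer ones, and the shares over 1 Mb are not a separate observation.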
